A study of Mus musculus with 6 samples.

How the data were processed

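The study measured total RNA from whole biceps muscle of CD-1 mice. One brachial plexus was excised on postnatal day 5, and both biceps were harvested on postnatal day 26, which gives 3 denervated and 3 contralateral control libraries from 3 mice. Per the labels' protocols, RNA was amplified with the Ovation RNA-Seq system, made into Nextera XT libraries and sequenced as paired-end reads of 75 bases, with a stated minimum of 35 to 40 M reads. The values are relative abundances, so a change in the share of a few abundant transcripts moves the values of all others.

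The authors deposited a table of 13105 genes with log2 values per library, per the file headers, and sheets of genes they list as up and down. Per the submitters' processing notes, kallisto 0.42.1 and the mm10 build were used. The step from transcripts to genes is not given in the sources used here, nor is the test behind the deposited p-values. No header names the unit of the log2 values the authors deposited. They were read as log2(TPM + 1), because kallisto gives TPM and the linear totals stay under the full TPM total in every library. The deposited log2 fold equals the difference of the group means to within 6.30e-11. The linear totals fell short of the full TPM total by 29.62% to 31.20% in control and by 19.66% to 22.75% in denervated libraries. Genes outside the table were not analysed here. Every listed gene reached at least 1.05 on the log2 scale in some library. The deposited table also carries a signed fold score per gene, which was not used here. Deposited p-values and adjusted p-values in the authors' table are quoted only where that table is named. A spreadsheet had turned 18 symbols into dates, which were restored by gene ID, 75 symbols were blank, and 19 symbols stood on more than 1 row. Of the gene IDs, 12862 were found in the table of gene names. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Every column of per-sample values was mapped to a sample by its name.

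Genes were tested where TPM was at least 1 in at least 3 of the 6 libraries, which left 12268. The deposited log2 values, with their pseudocount of 1, were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) with the group as the factor, and p-values were adjusted by the Benjamini-Hochberg method, with calls at 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. The test, the filter, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Because the median gene moved by 0.71, each gene is also given after median-of-ratios scaling, with factors of 0.720, 0.785 and 0.693 for control replicates 1 to 3 and 1.59, 1.27 and 1.27 for denervated replicates 1 to 3. In all, 41 lists were fixed, of which 26 are gene groups, 14 are cell type markers and 1 reads RNA quality, and the 38 with at least 3 tested members were tested with camera at a preset correlation of 0.01. Camera compares a list with all other genes, which lessens the effect of a shift common to all genes but does not remove it. It compares the t statistics of a list with those of the other genes, without ranking them. A common shift adds more to a t statistic where the spread is small, so list calls can differ between the scales. The counts of risen and fallen list members refer to genes called on both scales. A member called lower after scaling alone is therefore not counted as fallen.

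The genes named by rule are the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 TPM and the same direction in all 3 mice, leaving out predicted genes and pseudogenes. From each list called by camera or with at least 3 members past the threshold in one direction, up to 3 called members with the largest change and the most abundant member are named, and 21 genes are always named. Those include Chrna1, Chrng, Chrne, Myog, Runx1, Ncam1, Myh3, Myh8, Myh1, Myh2, Myh4, Myh7, Fbxo32, Trim63, Mstn, Cdkn1a, Gadd45a, Col1a1 and Pax7. Some of the genes so chosen are not reported here. Of the 141 genes so named, 70 were called higher and 30 lower on both scales and 41 were not. A further 26 genes were chosen after their values were seen, as stated beside those reported. The share of each gene's 31-mers that also occur in another gene was computed from the GENCODE M21 transcripts, as a guide to reads that kallisto has to split between genes.

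Both muscles of a mouse carry the same number in the labels, and the pairing comes from those labels. The deviations of same-mouse libraries from their group means correlated across genes at 0.312, 0.183 and 0.411 for mice 1, 2 and 3, all above 0.1. Genes are not independent replicates, so this is a check of the pairing alone. The Y-linked gene Ddx3y measured 9.30 and 13.4 TPM in the control and denervated muscle of mouse 2, and between 0.312 and 0.530 TPM in the other 4 libraries, so that both muscles of a mouse match in this respect. Eif2s3y, Kdm5d and Uty, also Y-linked, were likewise highest in both muscles of mouse 2. The labels give no sex, so it was not a factor in the fit. Leaving out mouse 2 also takes out this difference between mice. The fit with the mouse as a block is an alternative, and its adjusted p is given beside a gene where it changes a call.

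On simulated data with the real means and spreads of these 12268 genes, 200 were changed by known folds. These 200 were drawn from genes with a mean log2 value at or above that of 5 TPM, so recovery of lower genes is unknown. Without a common shift, the limma fit recovered 22.4% of those changed by 1.5-fold, 79.1% of those changed by 2-fold and 98.5% of those changed by 4-fold. Of its calls, 5.00% were unchanged genes. When all genes of one group were also raised by 2-fold, 91.2% of the unchanged genes were called on the unscaled values, and 0.0663% after median-of-ratios scaling. With that scaling the fit recovered 11.9%, 83.6% and 98.5% of the genes changed by 1.5-fold, 2-fold and 4-fold. The rule of a call on both scales was not simulated. In a simulation of 21 lists of which 1 was shifted, camera called that list and 0 of the 20 others. The run was set to stop unless the shifted list was called, so that call was required in advance. The same held for a high recovery at 4-fold without a common shift. The lists were simulated without a common shift, so camera under such a shift was not tried. The simulated noise was drawn independently for each gene. The simulation therefore says nothing of camera on lists whose members vary together, such as oxidative phosphorylation with an estimated correlation of 0.613. The alternatives were the mouse as a block, each library and each mouse left out, median-of-ratios and quantile scaling, removal of mitochondrially encoded genes, 2 other filters, pseudocounts of 0.1 and 0.5, eBayes without a trend and robust, and for lists an estimated correlation and fry. A count-based test was not run because the values are not counts. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.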

Results

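Whole biceps muscles of CD-1 mice were profiled by RNA sequencing 3 weeks after the brachial plexus of one forelimb had been excised on postnatal day 5. The excision leaves the growing biceps without its nerve. Both biceps of each of 3 mice were taken on postnatal day 26, so that the data hold 3 denervated muscles and 3 contralateral control muscles from the same animals. The deposited values are log2 abundances per gene, read here as log2(TPM + 1), where TPM is a length-normalized abundance that sums to a fixed total over all transcripts of a library. They carry no read counts, so the depth behind each value is unknown from the files, although the labels state a minimum of 35 to 40 M reads per library. The listed genes held 68.80%, 70.38% and 70.19% of the full TPM total in control replicates 1, 2 and 3. They held 80.34%, 79.35% and 77.25% in denervated replicates 1, 2 and 3. The comparison asks which transcripts differ between a growing muscle and a muscle whose growth was arrested on the way to contracture, as the series describes it.

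Denervated biceps carried far more of many transcripts of slow and developmental contractile proteins and of most acetylcholine receptor subunits than the control biceps. They carried far less of several transcripts of fast fibres, myelin and energy metabolism. Among called genes with a mean of at least 5 TPM, predicted genes left out, the largest rise was that of Sln, which encodes sarcolipin, a regulator of the sarcoplasmic reticulum calcium pump (ENSMUSG00000042045, chromosome 9: 53850164 to 53854560, plus strand, GRCm38), from 79.9 ± 7.88 to 1881 ± 417 TPM (mean ± SD, n = 3), with a log2 fold change of 4.52 ± 0.19 (SE) and a limma adjusted p of 7.59e-07. Next came Tnnc1 and Tnni1, the slow troponins C and I, with log2 fold changes of 4.47 and 4.42, Hamp2, a hepcidin gene (4.46), Tnnt2, cardiac troponin T (4.26), Igfn1 (4.20), Myl4, the embryonic and atrial myosin light chain (4.19), and the transcription factor Runx1 (4.15). Part of the signal of Hamp2 is uncertain, since 34.5% of its 31-mers occur in other genes. The large falls included those of Mlf1 (log2 fold change -3.04 ± 0.22, adjusted p = 1.03e-05), Dhrs7c (-2.95), the water channel Aqp4 (-2.83), the carbonic anhydrase Car14 (-2.82), Mettl21e (-2.82), Asb11 (-2.73) and Ckmt2, the mitochondrial creatine kinase of striated muscle (-2.61), which went from 749 ± 56.3 to 122 ± 0.778 TPM. Each of these genes moved the same way in all 3 mice.

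**Figure D1:**
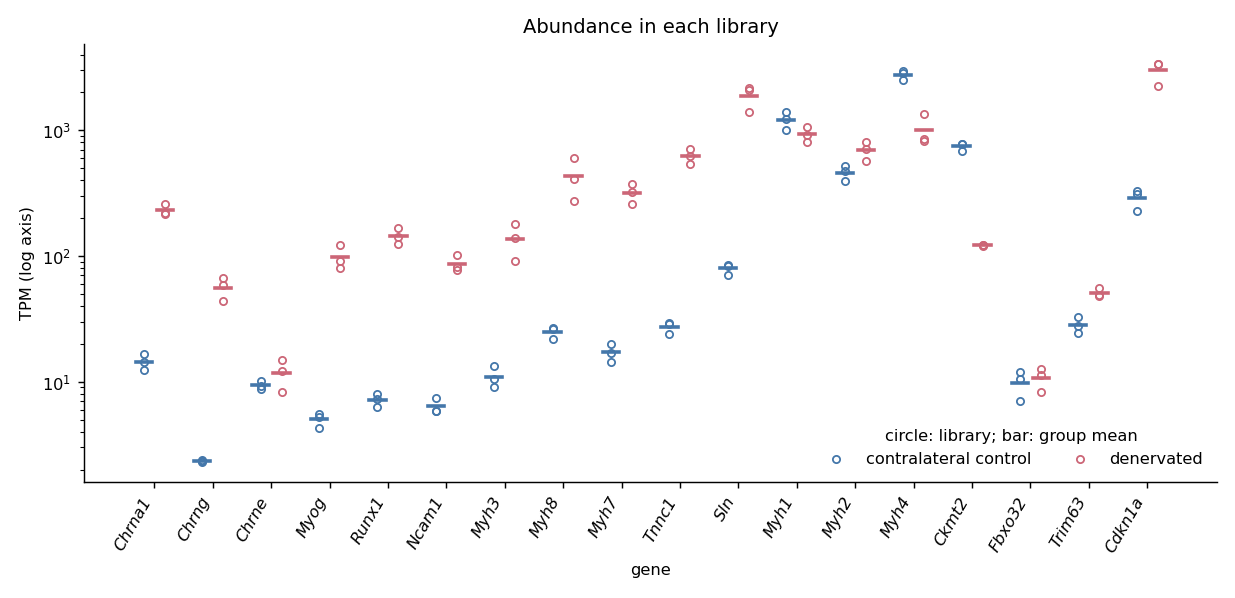
TPM of named genes in each library, on a log axis, colored by group; circles are libraries and bars are group means of 3 libraries. The denervated Chrna1 mean lies at 232 TPM against 14.4 TPM in control, while the Fbxo32 means are 10.7 and 9.84 TPM.

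Most genes stood higher in denervated muscle on the deposited scale. Of 12268 genes tested with limma, 10946 had a positive log2 fold change and the median was 0.71, so that 8580 genes were called higher and 552 lower at an adjusted p under 0.05 (93.96% higher), 3202 and 165 of them by at least 2-fold. Median-of-ratios scaling, which sets the typical gene to no change, brought the median to 0.01 and gave 1922 higher and 2280 lower genes (45.74% higher), with 540 and 817 by at least 2-fold. Rises are therefore described relative to this shift. A gene is said to have risen or fallen only where it was called in the same direction on both scales. That held for 1922 higher and 552 lower genes, and the rule was chosen after the shift had been seen. The rule is stricter for falls, which must also be called against the upward shift. All 1922 genes called higher after scaling met it, but only 552 of the 2280 called lower did. A count of 0 falls therefore does not exclude members lower after scaling. The higher count came to 1212 without denervated replicate 1 and 1262 without denervated replicate 3, and to 841 and 844 without both libraries of mouse 1 and of mouse 3. The log2 fold changes below are on the deposited scale unless called scaled, and a scaled value refers to median-of-ratios scaling.

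**Figure D2:**
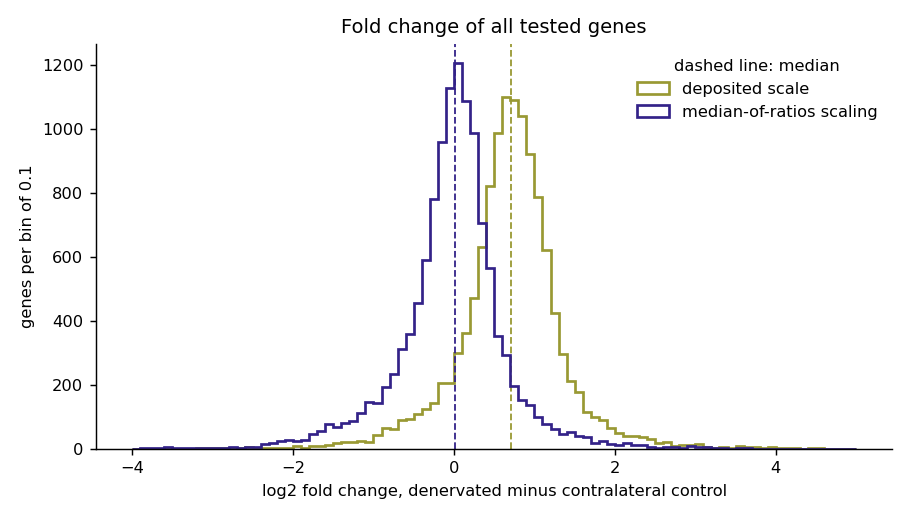
Number of genes per bin of 0.1 in log2 fold change, denervated minus contralateral control, for the 12268 tested genes on the deposited scale and after median-of-ratios scaling. The dashed medians lie at 0.71 and 0.01.

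Most genes of the acetylcholine receptor and the endplate rose. Of 16 measured members, 10 rose and 1 fell on both scales (10 and 1 adjusted over the list alone). Chrng, the fetal gamma subunit, went from 2.34 ± 0.0432 to 56.1 ± 11.6 TPM (SD, n = 3; log2 fold change 4.07, scaled 3.30). Chrna1 (ENSMUSG00000027107, chromosome 2: 73563215 to 73580338, minus strand) went from 14.4 ± 2.02 to 232 ± 24.6 TPM (log2 fold change 3.92, scaled 3.05), and Chrnd from 5.12 ± 0.270 to 84.3 ± 14.7 TPM. Ncam1, the neural cell adhesion molecule that muscle carries outside the synapse after denervation, went from 6.40 ± 0.913 to 86.5 ± 12.6 TPM, and the receptor kinase Musk from 5.28 ± 1.36 to 49.0 ± 5.80 TPM. Chrne, the adult epsilon subunit, measured 9.38 ± 0.711 TPM in control and 11.7 ± 3.27 TPM in denervated muscle (adjusted p = 0.252), with a log2 fold change of 0.26 that turned to -0.56 after scaling (adjusted p = 0.0282). The member that fell, named after its values were seen, was Ache, the acetylcholinesterase (scaled log2 fold change -2.04). Chrne was called higher on the deposited scale without denervated replicate 2 (adjusted p = 0.0349). Against all other genes, the endplate list stood higher in limma's camera test and had a camera adjusted p of 0.0210, and adjusted p = 0.838 with an estimated correlation.

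Transcription factors tied to myogenesis and denervation showed 8 rises and 1 fall among 15 measured members (8 and 1 adjusted over the list alone). Runx1 went from 7.20 ± 0.858 to 145 ± 20.6 TPM (SD, n = 3), Myog, the myogenic factor myogenin, from 5.01 ± 0.681 to 98.6 ± 21.9 TPM with a scaled log2 fold change of 3.21, and the histone deacetylase Hdac4 from 5.46 ± 0.538 to 52.7 ± 7.80 TPM, although 21.9% of the 31-mers of Hdac4 occur in other genes. The most abundant member, Mef2c, went from 128 ± 7.17 to 286 ± 32.0 TPM, and its scaled call was lost in the fit with the mouse as a block (adjusted p = 0.0776). Nr4a1, named after its values were seen, fell (scaled -2.12). Camera did not call this list on the deposited scale (adjusted p = 0.0800; adjusted p = 0.838 with an estimated correlation). It was called after scaling (adjusted p = 0.00786), and on the deposited scale without control replicate 3, denervated replicate 2, or mouse 2 or 3 (smallest adjusted p = 4.21e-05). Ion channels and transporters went both ways, with 4 rises and 4 falls among 14 members (5 and 4 adjusted over the list alone). The potassium channel Kcnn3 went from 2.56 ± 0.234 to 44.1 ± 2.03 TPM. Cacng1 also rose, while Clcn1, Kcnj2 and Aqp4 fell, with scaled log2 fold changes of -1.73, -1.56 and -3.56. Cacng1, Clcn1 and Kcnj2 were named after their values were seen. Fxyd1, the most abundant member, measured 431 ± 84.5 TPM in control and 642 ± 87.2 TPM in denervated muscle, and its log2 fold change went from 0.58 to -0.32 with scaling. Camera did not call this list (adjusted p = 0.187).

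Contractile genes separated by fibre type. All but 1 of the 8 developmental sarcomere genes rose (7 on both scales, 7 higher and 1 lower adjusted over the list alone). The developmental list had a camera adjusted p of 0.0132, and adjusted p = 0.694 with an estimated correlation. Myh8, the perinatal myosin heavy chain, went from 25.1 ± 2.74 to 429.8 ± 164 TPM (SD, n = 3), Myh3, the embryonic one, from 11.0 ± 2.22 to 136 ± 43.9 TPM, Tnnt2 from 12.4 ± 3.03 to 284 ± 177 TPM and Myl4 from 23.2 ± 2.83 to 461 ± 163 TPM. The exception, Actc1, cardiac actin, measured 1226 ± 215 TPM in control and 886 ± 219 TPM in denervated muscle (log2 fold change -0.48, adjusted p = 0.0575, or 0.00583 with the mouse as a block). Actc1 was also called lower without control replicate 2, denervated replicate 1, or mouse 1 (smallest adjusted p = 0.0170). Among 12 slow contractile and calcium handling genes 10 rose and 0 fell (10 and 0 adjusted over the list alone). The slow list had a camera adjusted p of 1.44e-04, and adjusted p = 0.554 with an estimated correlation. Tnnt1 went from 129 ± 8.49 to 1875 ± 196 TPM, Tnni1 from 37.5 ± 3.13 to 832 ± 167 TPM, Tnnc1 from 27.3 ± 2.77 to 628 ± 87.0 TPM and Myh7, the slow myosin heavy chain, from 17.1 ± 2.70 to 318 ± 55.7 TPM. Of the 31-mers of Myh7, 27.9% occur in other genes, and 22.5% of all occur in Myh6, so the level of Myh7 is uncertain.

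Fast contractile and calcium handling genes, the fast list, moved the other way, with 12 of 16 members falling and 0 rising on both scales (12 and 0 adjusted over the list alone). The fast list had a camera adjusted p of 1.27e-17, and adjusted p = 0.281 with an estimated correlation. Mybpc2, fast myosin binding protein C, went from 342 ± 48.5 to 57.6 ± 15.0 TPM (SD, n = 3), the myosin light chain kinase Mylk2 from 34.5 ± 3.76 to 8.67 ± 1.33 TPM and Myh4, the fastest myosin heavy chain, from 2776 ± 221 to 1012 ± 295 TPM. Myh1 measured 1210.3 ± 190.1 TPM in control and 930.4 ± 133 TPM in denervated muscle, with a log2 fold change of -0.38 (adjusted p = 0.0713, or 0.0210 with the mouse as a block) and a scaled value of -1.28. Myh1 was called lower without control replicate 3, or denervated replicate 1 (smallest adjusted p = 0.0342). Myh2 measured 461 ± 63.1 TPM in control and 696 ± 123 TPM in denervated muscle, and its log2 fold change of 0.59 turned to -0.31 with scaling. Myl1, the most abundant member at 10328 ± 1470.2 TPM in denervated muscle, likewise went from 0.71 to -0.19. The myosin heavy chains lie side by side on chromosome 11 and share sequence, with 42.9%, 34.5% and 30.4% of the 31-mers of Myh1, Myh2 and Myh4 found in other genes, so their split is uncertain. Genes of the Z-disc, titin and mechanosensing group were mixed, with 4 rises and 3 falls among 25 (4 and 3 adjusted over the list alone; camera adjusted p = 0.508). Ankrd1, a stretch-responsive ankyrin repeat protein, went from 17.5 ± 2.62 to 189 ± 12.4 TPM, Myom3 from 15.7 ± 3.25 to 106 ± 16.2 TPM and Lmod2 from 87.1 ± 6.13 to 340.1 ± 34.9 TPM, and Klhl41 also rose (scaled 0.40). Myot, Ldb3 and Myom1 fell (scaled -2.32, -1.50 and -1.47). Those 3 and Klhl41 were named after their values were seen. The call of Ldb3 was lost without mouse 3 (adjusted p = 0.0633), and that of Myom1 without control replicate 1, or mouse 1 (largest adjusted p = 0.0681). The most abundant member, Neb, measured 2783 ± 257 TPM in control and 5136 ± 675 TPM in denervated muscle, with a log2 fold change of 0.88 that became -0.02 after scaling.

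Genes of energy metabolism were lower in denervated muscle, most widely those of the respiratory chain. On both scales 37 of 41 nuclear genes of oxidative phosphorylation fell and 0 rose (37 and 0 adjusted over the list alone), and the list median was -1.61 after scaling. Cox7a1 went from 952 ± 88.4 to 465 ± 27.2 TPM (SD, n = 3), Cox5a from 662 ± 51.8 to 326 ± 22.0 TPM, Sdhb from 162 ± 14.7 to 82.4 ± 4.81 TPM and Atp5b, the most abundant member, from 4493 ± 23.2 to 3224 ± 129.7 TPM. The call of Atp5b was lost without control replicate 1 or 2, or mouse 2 or 3 (largest adjusted p = 0.0910). In glycolysis and glycogen metabolism 14 of 20 genes fell and 0 rose (14 and 0 adjusted over the list alone), among them Fbp2, Slc2a4, the insulin-responsive glucose transporter, Eno3, muscle enolase, and Aldoa, with scaled log2 fold changes of -2.48, -2.32, -2.24 and -1.87. In fatty acid oxidation, the tricarboxylic acid cycle and their regulators 16 of 27 genes fell and 0 rose (16 and 0 adjusted over the list alone), with Acaa2 going from 92.4 ± 2.32 to 38.1 ± 3.37 TPM, Idh3a from 103 ± 4.80 to 51.7 ± 4.51 TPM and Mdh2 from 575 ± 52.7 to 314 ± 26.5 TPM. Pdk4, the kinase that shuts pyruvate dehydrogenase, measured 58.0 ± 18.2 TPM in control and 138 ± 23.0 TPM in denervated muscle, a log2 fold change of 1.26 (adjusted p = 8.99e-04) that came to 0.37 after scaling (adjusted p = 0.309, or 0.0346 with the mouse as a block). Camera gave adjusted p = 1.34e-57, 5.73e-27 and 3.96e-27 for these 3 lists in turn. Each came to adjusted p = 0.277 with an estimated correlation. The marker lists of myelinating Schwann cells, endothelium and erythroid cells were also called lower, with values given beside those markers.

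Transcripts encoded in the mitochondrial genome, which also serve as a sign of RNA quality, moved with these groups. All 9 measured members of that list fell on both scales (9 adjusted over the list alone; camera adjusted p = 1.65e-14, and 0.0782 after quantile normalization). The list came to adjusted p = 0.281 with an estimated correlation. mt-Co1 went from 45046 ± 5373 to 24755 ± 2899 TPM (SD, n = 3), mt-Co3 from 12405 ± 833 to 7028 ± 791 TPM and mt-Nd2 from 4907 ± 601 to 2778 ± 236 TPM. Part of their sequence has copies elsewhere in the annotation, at 63.9% of the 31-mers of mt-Co1 and 99.9% of those of mt-Co3, so these levels are uncertain. The share of the full TPM total taken by all mitochondrially encoded genes did not part the groups, at 25.01%, 23.11% and 32.83% in the control libraries and 15.89%, 26.92% and 23.94% in the denervated ones. mt-Atp8 alone made up between 4.48% and 17.57% of a library, and without it the shares were 15.41% to 18.41% in control and 9.35% to 11.41% in denervated muscle.

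Neither of the ubiquitin ligases best known from muscle atrophy was called higher on both scales. Fbxo32, atrogin-1, measured 9.84 ± 2.53 TPM in control and 10.7 ± 2.23 TPM in denervated muscle (SD, n = 3; log2 fold change 0.13, adjusted p = 0.607), or -0.69 after scaling (adjusted p = 0.0499). Trim63, MuRF1, measured 28.4 ± 4.39 TPM in control and 51.0 ± 4.27 TPM in denervated muscle, a log2 fold change of 0.83 (adjusted p = 0.00122) that became -0.04 after scaling (adjusted p = 0.859). Of the 17 measured members of the ligase list, which also holds the receptor kinase Musk, 4 rose and 2 fell on both scales (4 and 2 adjusted over the list alone; camera adjusted p = 0.914). Fbxo30 went from 7.50 ± 0.508 to 27.9 ± 4.55 TPM, Nedd4 from 85.6 ± 11.2 to 254 ± 30.5 TPM and Mdm2 from 21.7 ± 2.49 to 66.6 ± 12.5 TPM, and the remaining rise was that of Musk, which is not a ligase and also belongs to the endplate list. Fbxo31 and Asb2, named after their values were seen, fell (scaled -1.46 and -1.44). The call of Asb2 was lost without control replicate 1 or 3, denervated replicate 2 or 3, or mouse 3 (largest adjusted p = 0.0905). Proteasome subunits rose in 12 of 36 cases and fell in 0 (13 and 0 adjusted over the list alone), led by Psmc3 (from 34.0 ± 2.30 to 102 ± 14.5 TPM), Psmc2 and Psmc4. The most abundant subunit, Psmb6, measured 94.3 ± 10.7 TPM in control and 169 ± 20.9 TPM in denervated muscle, and its log2 fold change of 0.83 became -0.06 with scaling. Camera called the list on the deposited scale (adjusted p = 0.00125) but not after scaling (adjusted p = 0.0738). It came to adjusted p = 0.838 with an estimated correlation. Chaperones of sarcomere assembly showed 6 rises and 0 falls among 13 (7 and 0 adjusted over the list alone). The chaperone list had a camera adjusted p of 0.0242, and adjusted p = 0.683 with an estimated correlation. It was not called after scaling (adjusted p = 0.114), with mitochondrially encoded genes removed (0.0638) or with the filter on a mean of at least 5 (0.0919). Hspb8, a small heat shock protein, went from 87.4 ± 8.41 to 705 ± 163 TPM, Hsp90aa1 from 46.3 ± 11.8 to 145 ± 10.6 TPM and Hspb1 from 78.8 ± 7.03 to 204 ± 11.6 TPM, and 51.5% and 55.4% of the 31-mers of the last 2 occur in other genes, so their levels are uncertain.

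Markers of satellite cells and of their fusion rose in 10 of 15 cases and fell in 0 (11 and 0 adjusted over the list alone). The satellite cell list had a camera adjusted p of 0.00293, and adjusted p = 0.414 with an estimated correlation. Tmem8c, which encodes the fusion protein myomaker, went from 20.6 ± 3.84 to 346 ± 72.8 TPM (SD, n = 3), Gm7325, which encodes its partner myomixer, from 0.904 ± 0.512 to 25.3 ± 13.8 TPM, Cxcr4 from 2.97 ± 0.272 to 18.7 ± 4.81 TPM and Pax7, the satellite cell factor, from 0.615 ± 0.119 to 2.80 ± 0.730 TPM. In the group of TGF-beta, BMP and myostatin signalling 12 of 24 genes rose and 0 fell (12 and 0 adjusted over the list alone). The follistatin gene Fst went from 5.12 ± 0.558 to 74.3 ± 28.2 TPM, Id2 from 1.38 ± 0.382 to 13.9 ± 2.52 TPM and Gdf5 from 0.175 ± 0.0163 to 6.13 ± 0.787 TPM, and 39.7% of the 31-mers of Gdf5 occur in other genes. Mstn, myostatin, measured 13.2 ± 3.27 TPM in control and 9.28 ± 2.94 TPM in denervated muscle, with a log2 fold change of -0.48 (adjusted p = 0.0855) and -1.30 after scaling (adjusted p = 9.33e-04). Mstn was called lower on the deposited scale without denervated replicate 1, or mouse 1 (smallest adjusted p = 0.0213). The signalling list had a camera adjusted p of 0.0208, and adjusted p = 0.838 with an estimated correlation. Its call was lost without denervated replicate 1 (adjusted p = 0.0552) and with no filter on low values (adjusted p = 0.0548).

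Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 289 ± 55.2 to 3000.0 ± 648 TPM (SD, n = 3; ENSMUSG00000023067, chromosome 17: 29090976 to 29100727, plus strand) with a log2 fold change of 3.37 ± 0.21 (SE) and a scaled value of 2.47. Gadd45a, a growth arrest and DNA damage gene, went from 18.2 ± 2.27 to 271 ± 32.4 TPM and the receptor Eda2r from 4.12 ± 0.511 to 67.5 ± 5.48 TPM. Among the 14 measured genes of growth arrest and p53, 7 rose and 2 fell (7 and 2 adjusted over the list alone), the falls being those of Ccng1 and Gadd45g, named after their values were seen (scaled -1.61 and -1.44). The call of Gadd45g was lost without control replicate 2 or 3, denervated replicate 1 or 2, or mouse 2 (largest adjusted p = 0.158). Camera gave the growth arrest list adjusted p = 0.285 on the deposited scale and 0.0470 after scaling, a call lost with the mouse as a block (adjusted p = 0.0504), and adjusted p = 0.838 with an estimated correlation. It was called higher on the deposited scale without mouse 2 or 3 (smallest adjusted p = 3.81e-04). The list of insulin-like growth factor, insulin and mTOR signalling showed 6 rises and 0 falls among 21 (7 and 0 adjusted over the list alone; camera adjusted p = 0.102). That list was called higher without control replicate 2, or mouse 2 or 3 (smallest adjusted p = 0.00231). With all libraries and an estimated correlation, camera gave it adjusted p = 0.838. The rises include those of the binding proteins Igfbp2 and Igfbp5 (scaled 1.98 and 1.09). The largest, that of Igfn1 (from 8.53 ± 0.633 to 177 ± 40.8 TPM), belongs to a muscle protein with immunoglobulin-like and fibronectin domains that is not a growth factor. Of 13 measured cell cycle genes 0 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.429), the fall being that of Aurka, named after its values were seen. Its call was lost without control replicate 2 or 3, denervated replicate 1 or 3, or mouse 1 or 3 (largest adjusted p = 0.267). Mcm6, Pcna and Rrm2 had scaled log2 fold changes of 0.45, 0.07 and 0.28 with adjusted p of 0.223, 0.656 and 0.216.

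Collagen and other matrix genes were not called as a list. Col1a1 measured 193 ± 114 TPM in control and 308 ± 156 TPM in denervated muscle (SD, n = 3; log2 fold change 0.71, adjusted p = 0.160, or 0.00901 with the mouse as a block), and -0.19 after scaling (adjusted p = 0.796). Col1a1 was called higher on the deposited scale without control replicate 2, denervated replicate 3, or mouse 2 or 3 (smallest adjusted p = 7.97e-04). Sparc, the most abundant member, measured 810.3 ± 352 TPM in control and 1181 ± 277 TPM in denervated muscle (adjusted p = 0.0840, or 0.0104 with the block), with log2 fold changes of 0.60 and, scaled, -0.30. It was called higher on the deposited scale without control replicate 2, denervated replicate 3, or mouse 2 or 3 (smallest adjusted p = 0.00268). Only 2 of 23 matrix genes rose on both scales, Timp1 and Loxl1, and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.637). Without mouse 3 camera called the list higher (adjusted p = 0.0320). With all libraries and an estimated correlation the list came to adjusted p = 0.954. Lum had a log2 fold change of 1.47, or 0.59 after scaling (adjusted p = 0.160). Basement membrane genes had 1 rise, that of Itgb1 (from 55.4 ± 11.9 to 153 ± 13.8 TPM), and 0 falls among 21 (1 and 0 adjusted over the list alone; camera adjusted p = 0.476). Dmd and Itga7 had scaled log2 fold changes of 0.39 and 0.38 (adjusted p = 0.0896 and 0.110; with the block the former came to 0.0280). Matrix proteases and their inhibitors had 3 rises, those of Timp1, Mmp2 and Mmp3, and 1 fall, that of Adamts8 (scaled -2.52), among 12 (5 and 1 adjusted over the list alone; camera adjusted p = 0.779). Mmp3 was named after its values were seen. Timp2 had a scaled log2 fold change of 0.61 (adjusted p = 0.0570, or 0.0135 with the block).

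Markers of the other cells of a whole muscle did not move as one. Markers of myelinating Schwann cells fell in 3 of 7 cases and rose in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 6.12e-07). The myelin list came to adjusted p = 0.281 with an estimated correlation. The falls included those of Mbp (from 17.8 ± 5.66 to 2.69 ± 0.755 TPM; SD, n = 3) and Ncmap. Pmp22 measured 74.4 ± 32.1 TPM in control and 48.4 ± 10.8 TPM in denervated muscle (adjusted p = 0.107, or 0.0102 with the mouse as a block). It was called lower without control replicate 3, or mouse 3 (smallest adjusted p = 0.0176). Markers of repair Schwann cells rose in 3 of 6 cases and fell in 0, Gdnf, Runx2 and Ncam1, the last of which muscle itself carries (4 and 0 adjusted over the list alone). Camera gave the repair list adjusted p = 0.213, 0.0295 after scaling, and adjusted p = 0.838 with an estimated correlation. No endothelial marker of 12 passed the limma test on the deposited scale at an adjusted p under 0.05, and 10 were lower after scaling (0 higher and 0 lower adjusted over the list alone). The endothelial list had a camera adjusted p of 1.44e-04, and adjusted p = 0.683 with an estimated correlation. Pecam1 measured 21.2 ± 4.43 TPM in control and 21.8 ± 3.75 TPM in denervated muscle, a log2 fold change of 0.04 that turned to -0.82 after scaling. Adipocyte markers rose in 6 of 11 cases and fell in 0 (8 and 0 adjusted over the list alone), with Adipoq going from 13.1 ± 6.13 to 67.7 ± 21.2 TPM, Cfd from 39.3 ± 20.6 to 189.8 ± 58.6 TPM and Scd1 from 28.5 ± 6.65 to 185 ± 38.9 TPM. Camera gave the adipocyte list adjusted p = 0.285, 0.0242 after scaling, and adjusted p = 0.871 with an estimated correlation. It was called on the deposited scale without control replicate 3, denervated replicate 2, or mouse 2 or 3 (smallest adjusted p = 2.17e-05). Fabp4 had a scaled log2 fold change of 0.18 (adjusted p = 0.658). Hemoglobin and other erythroid genes fell in 1 of 5 cases, Hbb-b1, and rose in 0 (0 and 0 adjusted over the list alone). The erythroid list had a camera adjusted p of 1.72e-05, and adjusted p = 0.414 with an estimated correlation. Of the 31-mers of Hbb-b1, 54.4% occur in other genes, and its call was lost without control replicate 1 or 2, denervated replicate 2 or 3, or mouse 1 or 2 (largest adjusted p = 0.151).

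Macrophage markers had 0 rises and 0 falls among 11 on both scales (0 and 0 adjusted over the list alone; camera adjusted p = 0.914), with 8 higher on the deposited scale alone. Cd68, Tyrobp and C1qb had scaled log2 fold changes of 0.99, 0.15 and 0.06 (adjusted p = 0.109, 0.781 and 0.893, the first 0.0208 with the mouse as a block). Lyz2, the most abundant, measured 64.1 ± 29.8 TPM in control and 98.5 ± 20.7 TPM in denervated muscle (SD, n = 3; adjusted p = 0.0536, or 0.00840 with the block), and was called higher without control replicate 2, denervated replicate 3, or mouse 2 or 3 (smallest adjusted p = 3.33e-04). Of its 31-mers, 32.8% occur in other genes. Fibroadipogenic markers had 0 rises and 0 falls among 12 (0 and 0 adjusted over the list alone; camera adjusted p = 0.367), with scaled log2 fold changes of 0.26 for Gsn, 0.20 for Hsd11b1 and -0.23 for Dcn, whose deposited value was 0.67 (adjusted p = 0.0592, or 0.0158 with the block). Dcn was called higher without control replicate 2, denervated replicate 3, or mouse 2 or 3 (smallest adjusted p = 5.45e-04). Among 10 mural markers 1 fell, Rgs5 (from 131 ± 23.1 to 77.0 ± 13.9 TPM), and 0 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.213), while Mcam and Notch3 had scaled values of -0.03 and 0.38. Tenocyte markers had 1 rise, that of Scx, named after its values were seen (from 3.56 ± 0.444 to 18.4 ± 4.36 TPM), and 0 falls among 9 (1 and 0 adjusted over the list alone; camera adjusted p = 0.102). Camera placed the tenocyte list lower, with a scaled median of -0.44, and called it lower without control replicate 1, or denervated replicate 2 (smallest adjusted p = 0.0134). With all libraries and an estimated correlation it came to adjusted p = 0.838. Among 6 neutrophil and mast cell markers S100a8 rose, from 3.19 ± 1.02 to 42.8 ± 15.6 TPM, the only one called on both scales. On the deposited scale 3 were higher and 0 lower, and after scaling 1 was higher and 1 lower. Adjusted over the list alone, 1 was higher and 0 lower on both scales, and the camera adjusted p was 0.429. The mast cell genes Cpa3 and Tpsb2 had scaled values of 0.03 and 0.19. The 3 measured lymphocyte markers had 0 rises and 0 falls (0 and 0 adjusted over the list alone; camera adjusted p = 0.519). Lists of cartilage and bone, epidermis, and spindle or neuron markers had 1, 2 and 1 measured members and were not tested as lists. Trp63, of the epidermal list and named after its values were seen, went from 4.51 ± 0.277 to 44.7 ± 8.58 TPM. Only 2 of the 9 markers on that list were measured, so this rise does not tell whether epidermal tissue was present.

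**Figure D3:**
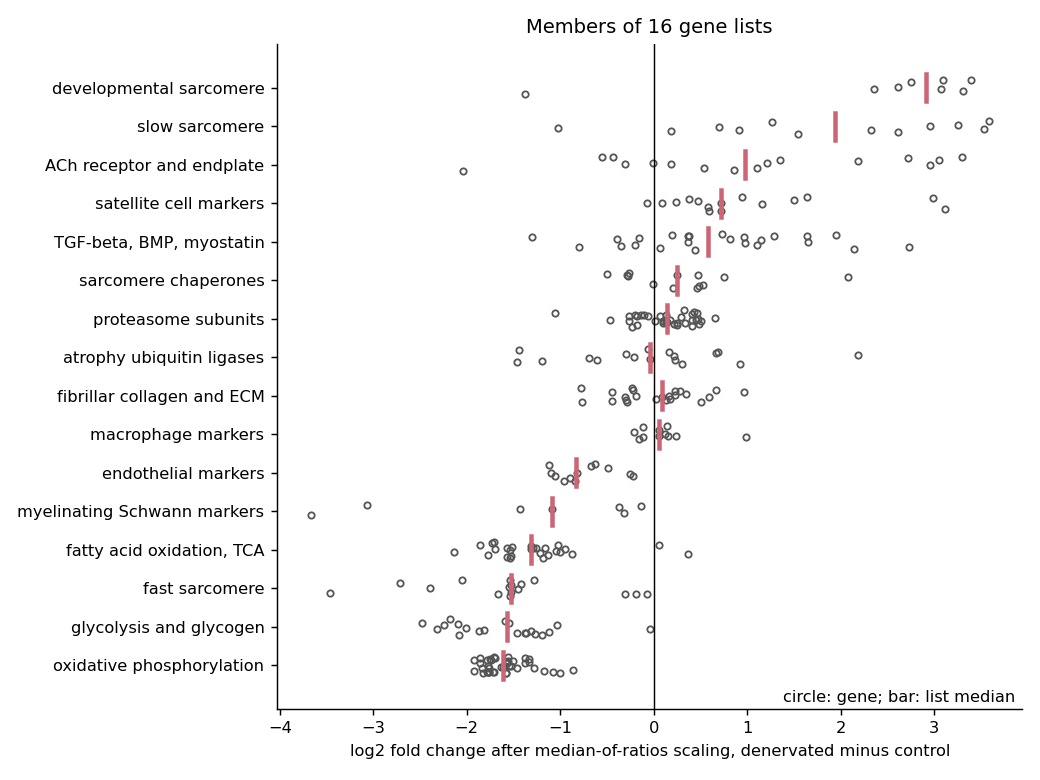
Log2 fold change after median-of-ratios scaling, denervated minus control, of each measured member of 16 gene lists; circles are genes and bars are list medians. The oxidative phosphorylation median lies at -1.61 and the slow sarcomere median at 1.94.

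Of 38 lists tested with camera, 7 were called higher and 8 lower in denervated muscle. Of these, 5 and 8 were also called after median-of-ratios scaling, and 0 of the 38 were called with an estimated correlation, where the smallest adjusted p was 0.277. With the preset correlation 18 lists had an unadjusted p under 0.05. The fry test, which does not set a list against other genes and so takes in the common shift, called 23 higher and 6 lower on the deposited scale. For the list of ion channels and transporters, fry called it higher there (adjusted p = 0.00397) and lower after scaling (fry adjusted p = 0.0386). The scaled median and mean differed in sign for the cell cycle list (0.02 and -0.03), the lymphocyte list (0.07 and -0.19) and the neutrophil and mast cell list (-0.23 and 0.16). The ligase list had both under 0 (-0.04 and -0.04) and a camera direction of higher. Camera's direction differed between the scales for the matrix, basement membrane, protease, cell cycle and macrophage lists. Camera called none of these 8 lists on either scale, the matrix list without mouse 3 aside. After scaling 6 ligase, 9 Z-disc, 4 TGF-beta and 3 fibroadipogenic list members were lower, against 2, 3, 0 and 0 falls on both scales. The authors' deposited table lists 336 genes as up and 21 as down. In the authors' deposited table these are the genes with a log2 fold of at least 2 in size, that is 4-fold, and a deposited adjusted p under 0.05. All 357 were called in the same direction by at least 2-fold in the limma fit. Direction and size were bound to match there, since both rest on the same values and the same folds, so only the adjusted p could differ. After median-of-ratios scaling 330 of the 336 and 21 of the 21 were still called by at least 2-fold. By at least 4-fold the scaled fit called 111 genes higher and 116 lower, against 342 and 21 on the deposited scale.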

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

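Scaling changed the counts of genes called in both directions. Against 8580 higher and 552 lower genes, median-of-ratios scaling gave 1922 and 2280, quantile normalization 2177 and 2106, and removal of mitochondrially encoded genes 5718 and 1055. By at least 2-fold, against 3202 and 165, these gave 540 and 817, 574 and 655, and 1272 and 373. With the replicate block added to median-of-ratios scaling, chosen after seeing the data, the counts were 1988 and 2342, or 556 and 828 by at least 2-fold. The filter on a mean of at least 5 gave 5047 higher genes because it tests fewer, and a pseudocount of 0.1 gave 4955 higher by at least 2-fold because it raises the folds of low genes. The replicate block on the deposited scale gave 8850 and 609. For lists, 7 were called higher, against 11 after quantile normalization, 6 to 13 with a library or mouse left out and 23 with fry. The fry count is on the deposited scale and takes in the common shift. An estimated correlation gave 0 higher and 0 lower, against 7 and 8. The genes called higher on both scales, 1922, ranged from 841 to 1833 with a library or mouse left out, a setting chosen after seeing the data.

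Over the named genes, 3022 of 3257 combinations of gene and setting kept direction and call, 136 lost the call, 53 gained it and 46 changed sign. After median-of-ratios scaling, with or without the block, the log2 fold change turned to -0.32 for Fxyd1, -0.059 for Psmb6, -0.19 for Myl1, -0.020 for Neb, -0.30 for Sparc, -0.21 for Lyz2, -0.82 for Pecam1, -0.031 for Mcam, -0.23 for Dcn, -0.56 for Chrne, -0.31 for Myh2, -0.69 for Fbxo32, -0.044 for Trim63 and -0.19 for Col1a1. With quantile normalization it turned to -0.0091 for Cpa3, -0.70 for Pecam1, -0.022 for Mcam, -0.52 for Chrne and -0.64 for Fbxo32, and with mitochondrially encoded genes removed to -0.34 for Pecam1, -0.11 for Chrne and -0.25 for Fbxo32. With a library or mouse left out, that of Oaz2 ran from -0.17 to 0.095, that of Pecam1 ran from -0.11 to 0.26 and that of Fbxo32 ran from -0.073 to 0.29, and the camera adjusted p of the matrix list from 0.0320 to 0.665, the lowest of these as a call in the higher direction without mouse 3. Median-of-ratios scaling lowers the fold changes of these genes by its construction, and the cause of the other sign changes was not tested. The replicate block changed the call of Actc1, Sparc, Lyz2, Dcn, Pmp22, Myh1 and Col1a1 on the deposited scale and of no other named gene there, and after scaling that of Mef2c, Foxo1, Atg12, Gabarapl1, Cd68, Dbp, Timp2, Dmd and Pdk4. It changed no list call on the deposited scale, and after scaling that of the growth arrest list alone. The list of myogenic and denervation factors was also called with quantile normalization, mitochondrially encoded genes removed and the filter on a mean of at least 5 (adjusted p = 0.00272, 0.0341 and 0.0388), and those of growth arrest, interferon and adipocytes with quantile normalization (0.0406, 0.0445 and 0.0210). DESeq2 and a transcript-level choice were not run, since the values are not counts and the rows are genes. Depth is unknown, so no limit from counting could be set on low genes.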

Other observations

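Of the tests in this part, those of the 3 shares of the TPM total, of the muscle fibre share, of the deposited pathways and of imprinted genes were chosen only after the result they bear on was seen. Of 14 measured genes of the list of interferon response and antigen presentation 6 rose and 0 fell on both scales (6 and 0 adjusted over the list alone). The rises include those of the class II genes H2-Ab1 (from 7.32 ± 3.41 to 42.2 ± 10.9 TPM; SD, n = 3) and H2-Aa (from 16.0 ± 8.29 to 81.7 ± 18.0 TPM), the invariant chain Cd74 (from 15.6 ± 6.15 to 80.7 ± 19.6 TPM) and B2m (from 131 ± 17.3 to 328 ± 53.2 TPM). The class I gene H2-D1, which shares sequence with other class I genes, and the interferon response gene Irf7 did not pass after scaling, with scaled log2 fold changes of 0.20 and 0.35 (adjusted p = 0.347 and 0.119). Both were named after their values were seen. Camera did not call the list on the deposited scale (adjusted p = 0.187) and gave adjusted p = 0.0353 after scaling, and adjusted p = 0.838 with an estimated correlation. The list was called on the deposited scale without denervated replicate 3, or mouse 2 or 3 (smallest adjusted p = 0.00175). Of 15 genes of ATF4 and endoplasmic reticulum stress 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.337), among them the amino acid transporter Slc7a5, Mthfd2, Psat1 and the chaperone Hspa5, with scaled log2 fold changes of 1.26, 1.14, 0.93 and 0.43. Autophagy and lysosome genes had 5 rises and 0 falls among 21 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0989). The rises were those of Map1lc3a (from 39.7 ± 3.20 to 173 ± 36.1 TPM), Ctsl, Foxo1, Atg12 and Gabarapl1, the last 2 named after their values were seen, and that of Foxo1 came to an adjusted p of 0.0518 after scaling with the mouse as a block. The same fit gave 0.0558 for Atg12 and 0.0641 for Gabarapl1. Ctsd, the most abundant, had a scaled value of 0.13. Of the 31-mers of Ctsl, Gabarapl1 and Ctsd, 28.2%, 25.2% and 33.2% occur in other genes, so these levels are uncertain.

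Clock genes had 4 rises and 0 falls among 15 (4 and 0 adjusted over the list alone; camera adjusted p = 0.429), those of Clock, Tef, Per2 and Per3, the last 2 named after their values were seen, with scaled log2 fold changes of 0.74, 0.52, 0.87 and 0.63. Nr1d1 and Dbp had scaled values of 0.08 and 0.92 (adjusted p = 0.466 and 0.123, the latter 0.00697 with the mouse as a block). Among 8 polyamine genes Odc1, ornithine decarboxylase, rose and Amd1, named after its values were seen, fell (scaled 0.48 and -1.61; 1 and 1 adjusted over the list alone; camera adjusted p = 0.578). The call of Amd1 was lost without control replicate 2, denervated replicate 1, 2 or 3, or mouse 1 or 2 (largest adjusted p = 0.282), and 82.8% of its 31-mers, and 31.3% of those of Odc1, occur in other genes. Srm, Oaz1 and Oaz2 had scaled values of 0.30, 0.23 and -0.90. Of 139 pathways that the authors' deposited table assigns to genes, 8 were called lower and 6 higher by camera, and 7 and 1 of these held after scaling. The one that held as higher was that of cytoplasmic ribosomal proteins, with 20 rises and 1 fall on both scales among 85 genes, a scaled median of 0.22 and an adjusted p of 0.000737, or 0.00249 after scaling. None of these calls held with an estimated correlation. Electron transport, oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis led the lower ones.

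The upward shift of the median gene, 0.71 on the deposited scale, or 0.61 to 0.76 with each library left out, was set against 3 technical explanations, each a class of transcripts that takes a smaller share of the full TPM total and so raises all others alike. The measured change in share of the mitochondrially encoded genes would give the others a log2 rise of 0.0905 (0.032 to 0.13 with each library left out), and that of genes outside the table a rise of 0.18 (0.17 to 0.19). Removing the mitochondrially encoded genes and rescaling the other listed genes to a common total brought the median to 0.39, a step that by its construction also takes out part of a rise common to the listed genes. The 200 most abundant genes held 54.33% to 56.73% of that total in control and 53.50% to 57.67% in denervated libraries, which would give -0.0058 (-0.039 to 0.029), although their share of the listed genes was 78.37% to 80.83% in control and 66.59% to 72.68% in denervated libraries, as the other listed genes held 13.46% to 15.23% and 21.68% to 26.84% of the full total. So none of these 3 shares alone, spread evenly over all other transcripts, accounts for the shift. The shares add to a fixed total, so a smaller share outside the table beside a flat share of the 200 genes goes with a larger share of the other listed genes. Taking 1 class at a time cannot weigh that combination. Whether the RNA of most genes rose or that of the remaining transcripts fell stays open, since no spike-in was used here.

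The real grouping called 9132 genes on the deposited scale. Of the 10 splits of the 6 libraries into equal groups, 1 reached that many, the real one, and the highest of the other splits called 18. After median-of-ratios scaling the real value was 4202 and the highest other 8. With 10 splits the share cannot go under 0.1. Every other split mixes denervated and control muscles in both groups, so the real difference adds to their spread and holds down their calls. Their low counts therefore do not measure how many genes would be called without a real difference. The 3 other splits that also part every pair of muscles each called 0 genes with limma, with 26, 78 and 33 genes at an unadjusted p under 0.05 on the deposited scale.

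The lower level of fast sarcomere, glycolysis, fatty acid oxidation and respiratory chain genes had a median scaled log2 fold change of -1.55 over 104 members, with quartiles of -1.77 and -1.29. If a lower share of muscle fibre RNA were the cause and the other cell types kept their proportions, their markers would rise alike. The adipocyte and endothelial medians, picked as the highest and lowest of the cell types compared, lay 1.85 apart (1.02 and -0.83). Their interquartile ranges did not overlap. The other cell types can also change among themselves, so this does not decide on a lower fibre share that comes with such changes. The trend of all other genes with GC content and transcript length was weak (R squared 0.855%) and gave the members a median of -0.05, so that taking it out left -1.50 (upper quartile -1.28), and the 58 members with under 5% of their 31-mers in other genes had a median of -1.58 (upper quartile -1.32). These values argue against GC content and length, and against shared sequence, as the whole cause. For the fibre share they argue only against a loss that leaves the proportions of the other cell types unchanged. A lower fibre share together with changes among the other cells stays open. The denervation that the design names stays open and was not tested apart from these.

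Peg3 and Zim1, imprinted neighbours singled out after their values were seen, went from 26.3 ± 1.00 to 251 ± 52.7 TPM and from 3.36 ± 0.237 to 33.5 ± 8.66 TPM (SD, n = 3). This suggested that imprinted genes of a fetal growth network might stay high in muscle whose growth was arrested. The other 15 measured members of such a list did not bear this out. On both scales 3 rose and 2 fell, and their scaled median was -0.13. The limma camera p was 0.469 after scaling and 0.442 on the deposited scale, both in the lower direction.

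A few transcripts took very different shares in libraries of the same group. mt-Atp8 measured 66080, 75113 and 174240 TPM in control replicates 1, 2 and 3 and 44799, 175730 and 130490 TPM in denervated replicates 1, 2 and 3. Atp5j measured 1753, 2011 and 6059 TPM and 1112, 5517 and 3610 TPM in the same libraries. Gm12338 was listed at 20000, 31279 and 0 TPM in control and 11126, 0 and 0 TPM in denervated muscle. Gm10222 and mt-Nd4l had identical values in every library, and all 264 of the 31-mers of Gm10222 occur in mt-Nd4l, so these 2 genes cannot be read separately. Gm12913, Gm15662 and Lars2, singled out after their values were seen, together held 7.38% to 11.29% of the full TPM total in control and 13.82% to 16.75% in denervated libraries. Their log2 fold changes of 0.59, 0.86 and 0.62 turned to -0.31, -0.04 and -0.28 after scaling (limma adjusted p = 0.309, 0.894 and 0.167).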
